A study of Mus musculus with 9 samples.

How the data were processed

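Total RNA from cultured mouse primary lung fibroblasts was hybridised to Affymetrix mouse whole-transcript gene arrays, 9 arrays in all. The labels give 3 untreated samples, 3 treated with TGFβ at 5 ng/ml and 3 treated with the chemokine CCL1 at 50 ng/ml, both for 48 h. TGFβ is named in the series design as the positive control. The labels do not say whether the 3 samples of a group came from separate cultures or animals. The p-values therefore measure only the spread between these samples, which can be technical. The labels give no hybridisation batch.

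The authors deposited 1 table of log2 expression values with 41345 rows for the 9 arrays. Per the submitters' processing notes, it was made with RMA in Affymetrix Expression Console 1.4.1. RMA corrects background, quantile-normalizes the arrays together and summarises the probes of each row. Its values are relative and cannot show a change in total RNA per cell, and high signals compress towards the ceiling of the scanner. The genome build behind the annotation is not given in the sources used here, so no coordinates are printed. The values run from 0.816 to 13.6, and the median of an array lies between 5.10 and 5.18. No detection call was used, and the number of arrays, not a read depth, limits the precision. Arrays of 1 group correlated with r between 0.981 and 0.989 over all rows, and no pair of arrays was identical. Arrays of different groups correlated as closely, with r between 0.983 and 0.989. The least similar pair of all was TGFβ replicates 1 and 2 (r = 0.981). The SD of the difference between any pair lay between 0.32 and 0.43 on the log2 scale.

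The platform annotation listed 23521 rows with 1 gene symbol, 1814 rows with several and left 16010 rows unnamed here. Entrez identifiers of 23328 of the single-gene rows were found in a RefSeq gene table of GRCm38.p6, which changed 0 symbols. Control rows could not be told from other unnamed rows, and none of these entered the gene tests. For the 1082 genes with more than 1 row, the row with the highest mean over all 9 arrays was used, which left 22180 genes. In 462 genes the rows disagreed in the sign of the TGFβ fold change.

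Each comparison was tested with limma 3.58.1 in R 4.3.3, by lmFit and eBayes on the deposited log2 values, in 1 model of the 3 groups over all 9 arrays. The model had 6 residual and 3.39 prior degrees of freedom, and the median SE of a log2 fold change was 0.11. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are given as log2 values with the limma SE, n = 3 arrays a group.

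A total of 27 gene lists covering 412 genes was fixed before the data were examined, and 382 of these genes had a row of their own here. The lists were tested with camera from limma at its preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. The estimated correlation and fry were run beside it. Members were also adjusted over the list alone.

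The genes named were set by a rule. For each stimulus against untreated, the 8 largest increases and 8 largest decreases among called genes whose 3 arrays all lay on one side of the other 3 were taken. If none passed, the 5 with the smallest p in that direction were taken. For CCL1 against TGFβ the number was 5 in each direction. Predicted and receptor-cluster genes were passed over. Up to 4 members of each list with the smallest p were added, and Acta2, Col1a1, Fn1, Ccl1, Ccr8 and Spry1 whatever their values. A further gene of the rule had no row of its own and is not analysed here. Genes named outside the rule are said to be so.

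The test was tried on simulated data drawn from the real means and residual SDs of the 22180 genes, with 200 genes changed in each of 10 runs. In the CCL1 against untreated comparison it called 35.4% of changes of 1.41-fold, 83.7% of 2-fold and 98.9% of 4-fold. The corresponding shares for TGFβ against untreated were 36.4%, 83.7% and 98.8%. Between 4.30% and 5.04% of the calls were false. These shares hold for 200 changed genes drawn independently. With fewer changed genes the Benjamini-Hochberg threshold is stricter, so the share called can be lower.

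The alternatives planned before the data were examined were a replicate block, only genes at or above the median brightness, another scaling to a common median, a further quantile normalization, the mean of a gene's rows, an intensity trend, array weights and leaving out each array. For gene calls they also covered only the 6 arrays compared, all rows, and a minimum fold. For lists they covered an estimated correlation and fry. Robust eBayes, the epithelial marker mean as a covariate and the removal of arrays that stood apart were added after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.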

Results

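Expression was measured in mouse primary lung fibroblasts, cells grown out of lung tissue that make and remodel extracellular matrix. There were 3 untreated samples, 3 samples kept with TGFβ at 5 ng/ml for 48 h and 3 kept with CCL1 at 50 ng/ml for 48 h. TGFβ is the classic profibrotic cytokine and served as the positive control, and CCL1 is a chemokine that binds the receptor CCR8. Each sample gave 1 array with log2 RMA values, and 22180 genes were tested. The cultures also carried transcripts of other lung cells. In the untreated samples the macrophage gene Lyz2 lay at 12.28 ± 0.08 and Cd68 at 10.59 ± 0.08, and the alveolar type II gene Sftpc at 10.96 ± 0.71 (log2, SD, n = 3). The smooth muscle actin gene Acta2 lay at 13.35 ± 0.03 in untreated cells, against a highest value of 13.64 in the whole table.

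The first comparison asked what TGFβ changed. TGFβ raised the chemokine gene Ccl17 3.98-fold (log2 fold change 1.99, SE 0.17, n = 3 and 3 arrays), from 5.12 ± 0.29 to 7.12 ± 0.20. It raised Tnfrsf11b, which encodes the decoy receptor osteoprotegerin, 2.59-fold (1.38, SE 0.11), and Has2, a hyaluronan synthase, 2.43-fold (1.28, SE 0.12). The vasodilator peptide gene Adm fell from 9.95 ± 0.20 to 8.46 ± 0.39 (log2 fold change -1.49, SE 0.18). The lymphatic growth factor gene Vegfd fell from 9.90 ± 0.19 to 8.71 ± 0.19 (-1.19, SE 0.15). In all, limma with Benjamini-Hochberg adjustment called 29 genes, 19 higher and 10 lower, of which 15 changed at least 2-fold. Unadjusted p-values under 0.05 numbered 2103, where 1109 would come by chance.

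The other large increases were Apol9b (1.60, SE 0.11), the protease inhibitor gene Tfpi2 (1.39, SE 0.17), the EGF-family ligand gene Hbegf (1.26, SE 0.13), the procollagen-processing protease gene Tll1 (1.14, SE 0.13) and the serotonin receptor gene Htr2b (1.12, SE 0.11). The other large decreases were the protease gene Adamts9 (-1.38, SE 0.17), Gp2 (-1.09, SE 0.15), the protein kinase A subunit gene Prkar2b (-1.02, SE 0.12), the transcription factor gene Atoh8 (-0.91, SE 0.11), Ezr, which encodes the membrane linker ezrin (-0.85, SE 0.10), and the retinaldehyde dehydrogenase gene Aldh1a1 (-0.82, SE 0.12). Limma adjusted p-values of these 16 genes lay between 0.00216 for Apol9b and 0.0491 for Aldh1a1. In each of the 29 called genes the 3 TGFβ arrays lay on one side of the 3 untreated arrays, which a call on so few arrays all but requires. Over all genes 11.9% showed this arrangement, where chance gives 10%.

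**Figure D1:**
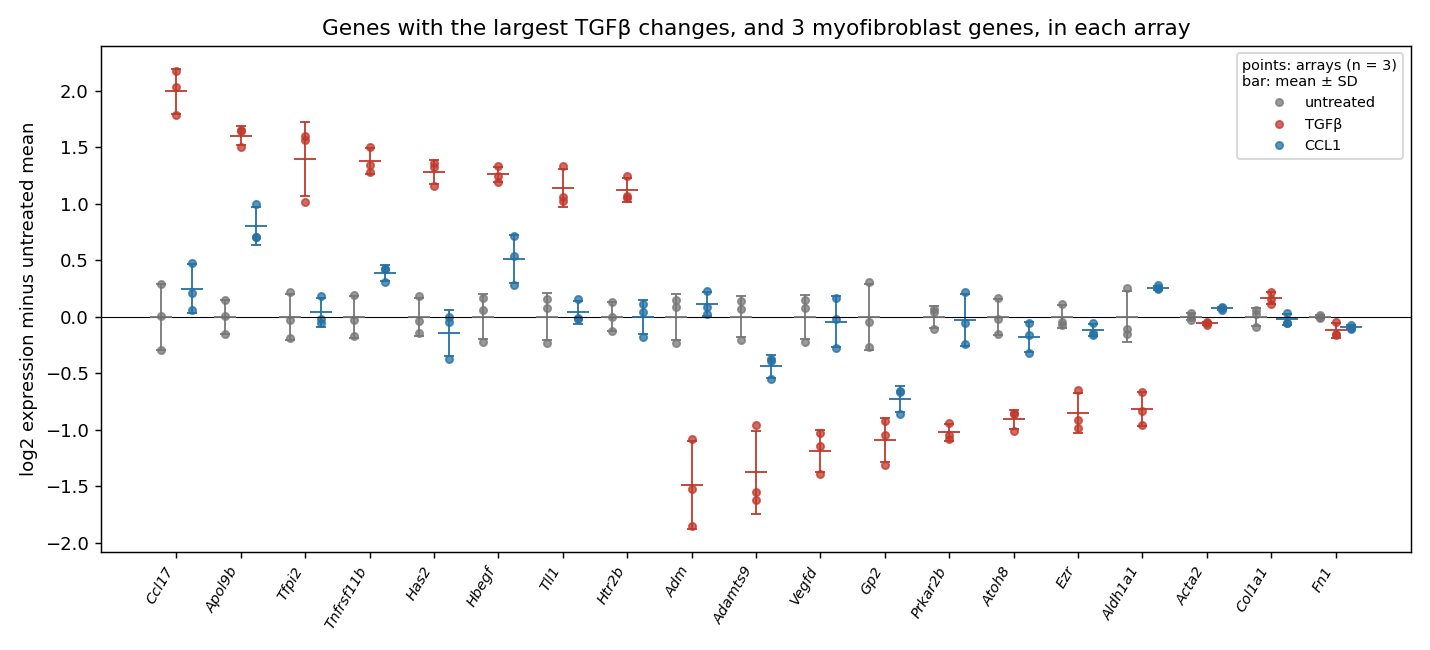
Log2 expression of 19 genes in each array, on the y axis as the difference from the mean of the untreated arrays, with genes on the x axis, arrays as points (n = 3 a group) and mean ± SD as bars. Ccl17 lay 1.99 higher after TGFβ and Adm had a difference of -1.49, while Acta2, Col1a1 and Fn1 stayed within 0.17 of the untreated mean in both stimulated groups.

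Classical myofibroblast genes did not pass. A rise of Acta2 could be hidden, since in untreated cells it lay near the highest value of the whole table (13.64), where signals compress. Acta2 had a log2 fold change of -0.06 (SE 0.07; 95% interval -0.21 to 0.09), the collagen gene Col1a1 0.17 (SE 0.08; -0.00 to 0.33) and the fibronectin gene Fn1 -0.12 (SE 0.07; -0.27 to 0.04), with limma adjusted p-values of 0.839, 0.540 and 0.654. Of the 20 collagen chains, 0 were called over all genes and 0 adjusted over the list alone. Among them Col11a1 had a log2 fold change of 0.63 (SE 0.18) and Col6a1 of -0.45 (SE 0.13). The list as a whole did not pass camera (adjusted p = 0.136). The 20 contractile genes did not pass either (camera adjusted p = 0.345). Acta1, the skeletal muscle actin gene, had the largest value in that list (1.16, SE 0.21, limma adjusted p = 0.0993). Adjusted over the list alone, 1 contractile gene was higher and 1 lower. The median of this list was -0.03 and its mean 0.01.

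Crosslinking enzymes and matrix glycoproteins shifted upward as lists. All 15 enzymes of collagen processing and crosslinking had positive fold changes, with a median of 0.16 (camera adjusted p = 2.00e-06, adjusted p = 0.0605 with an estimated correlation). Examples are the lysyl oxidase gene Lox (0.42, SE 0.10) and the procollagen protease gene Bmp1 (0.40, SE 0.09). Of these enzymes 0 were called over all genes and 4 were higher adjusted over the list alone. The 21 matrix glycoproteins had a median of 0.15 (camera adjusted p = 0.00105, adjusted p = 0.222 with an estimated correlation), with 7 higher and 1 lower adjusted over the list alone and 0 over all genes. Tgfbi had a log2 fold change of 0.94 (SE 0.20), Thbs2 of 0.81 (SE 0.15), Cthrc1 of 0.47 (SE 0.11) and Ccn2 of 0.38 (SE 0.08). Without TGFβ replicate 1 the glycoproteins did not pass (camera adjusted p = 0.133). Matrix proteases and inhibitors did not pass and had a median of -0.29 (camera adjusted p = 0.238), with 5 higher and 6 lower adjusted over the list alone and 0 over all genes, among them Adamts5 at -1.15 (SE 0.20) and Mmp14 at 0.42 (SE 0.09). Of the 21 TGFβ targets and feedback regulators, Hbegf, Pmepa1 (0.97, SE 0.11) and Sphk1 (0.66, SE 0.09) rose over all genes, and 7 were higher and 3 lower adjusted over the list alone. This list passed camera (adjusted p = 0.000213, adjusted p = 0.0605 with an estimated correlation), and fry found its members moving upward on balance (adjusted p = 0.00350). Of the 11 lists that passed camera for TGFβ, fry passed 3. The others were crosslinking enzymes (fry adjusted p = 0.00949) and DNA replication (0.0212), and the rest had fry adjusted p-values from 0.0707 to 0.604. Its member Id1, a BMP target, had a log2 fold change of -0.83 (SE 0.13, limma adjusted p = 0.0601).

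Cell cycle lists shifted downward after TGFβ. All 19 mitosis genes had negative fold changes, with a median of -0.24 (camera adjusted p = 5.05e-10, adjusted p = 0.222 with an estimated correlation). Examples are Cdk1 (-0.37, SE 0.09) and Top2a (-0.29, SE 0.09). All 19 DNA replication genes were negative too, with a median of -0.18 (camera adjusted p = 1.78e-08, adjusted p = 0.130 with an estimated correlation), among them Gins1 (-0.59, SE 0.12) and Pcna (-0.34, SE 0.09). Over all genes 0 members of both lists were called, while 5 mitosis and 3 replication genes were lower adjusted over the list alone. The 11 p53 targets and cell cycle inhibitors shifted upward, with a median of 0.04 and Cdkn2b, the p15 inhibitor, at 0.46 (SE 0.12). That list had a camera adjusted p of 0.0237, and adjusted p = 0.222 with an estimated correlation. It did not pass without untreated replicate 1 (0.0929), untreated replicate 2 (0.0741) or TGFβ replicate 1 (0.202).

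All 14 genes of serine, glycine and proline synthesis and ATF4 targets had positive values (median 0.24, camera adjusted p = 1.50e-06, adjusted p = 0.222 with an estimated correlation). Aldh18a1, an enzyme of proline synthesis, had a log2 fold change of 0.41 (SE 0.12). All 13 ER folding genes were positive (median 0.19, camera adjusted p = 2.06e-05, adjusted p = 0.222 with an estimated correlation), led by the chaperone gene Hyou1 (0.43, SE 0.08). Cholesterol synthesis genes shifted downward in 14 of 15 members (median -0.11, camera adjusted p = 0.00110, adjusted p = 0.499 with an estimated correlation), with Fdps at -0.39 (SE 0.11), and did not pass without TGFβ replicate 2 (camera adjusted p = 0.129). Mesothelial markers shifted downward in 7 of 8 (median -0.49, camera adjusted p = 5.29e-05, adjusted p = 0.222 with an estimated correlation), with Gpm6a at -1.40 (SE 0.38) and Wt1 at -0.47 (SE 0.09). Epithelial markers shifted downward in 13 of 13 (median -0.20, camera adjusted p = 0.0169, adjusted p = 0.623 with an estimated correlation), with Epcam at -0.68 (SE 0.29). Single arrays ended that call, namely untreated replicate 3 (camera adjusted p = 0.647), TGFβ replicate 1 (0.241) and TGFβ replicate 2 (0.406). Macrophage markers did not pass (median 0.03, camera adjusted p = 0.991).

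The number of TGFβ calls depended on single arrays. Without TGFβ replicate 1 it was 407, with 109 higher and 298 lower, a balance opposite to that of the 29, and without TGFβ replicates 2 or 3 it was 16 or 9, and without untreated replicates 1, 2 or 3 it was 8, 11 or 12. Leaving out the most epithelial array of each group, an alternative chosen after seeing the data, left 2 arrays a group and 0 calls. Unadjusted limma p-values under 0.05 numbered 938 there. The epithelial marker mean as a covariate, also chosen after seeing the data, kept all arrays and gave 22 calls. Of these, 21 were among the 29.

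The comparison at the centre of the study asked what CCL1 changed, and no gene passed. Apol9b had a log2 fold change of 0.80 (SE 0.11, n = 3 and 3 arrays), from 4.89 ± 0.15 to 5.70 ± 0.17. Vnn1, which encodes the pantetheinase vanin, had 0.75 (SE 0.11) and the lectin-like receptor gene Klra5 0.85 (SE 0.13). The thyroid hormone receptor gene Thrb had -0.48 (SE 0.09) and the chondroitin sulfotransferase gene Chst11 -0.61 (SE 0.12). Limma with Benjamini-Hochberg adjustment called 0 of 22180 genes, and the lowest limma adjusted p was 0.580. Unadjusted limma p-values under 0.05 numbered 1323 where 1109 would come by chance, an excess that depended on single arrays. The count was 958, 1461 or 936 without untreated replicates 1, 2 or 3. Without CCL1 replicates 1, 2 or 3 it was 1361, 1023 or 1117. The 95% interval of the log2 fold change lay inside -1 to 1 for 98.4% of genes.

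The remaining genes with the smallest p in each direction were Zfp456 (0.60, SE 0.11), Tmem171 (0.88, SE 0.16), Nlrp1c-ps (-0.84, SE 0.15), the chromatin remodelling gene Arid1b (-0.48, SE 0.09) and Sipa1l2 (-0.49, SE 0.09), each with an limma adjusted p of 0.767. The 3 CCL1 arrays lay on one side of the 3 untreated arrays in 12.7% of genes, where chance gives 10%. Acta2 had a log2 fold change of 0.07 (95% interval -0.07 to 0.22), Col1a1 -0.02 (-0.19 to 0.15) and Fn1 -0.09 (-0.25 to 0.06), with limma adjusted p-values of 0.910, 0.988 and 0.883. Here too a rise of Acta2 could be hidden by its high signal. The receptor gene Ccr8 lay at 3.85 ± 0.48 in untreated cells. That mean lay under the lower quartiles of all rows in those arrays (3.90 to 3.93), so a change could be missed. Ccr8 had a log2 fold change of 0.06 (SE 0.21), Ccl1 itself 0.07 (SE 0.14) and the signalling inhibitor gene Spry1 0.01 (SE 0.16).

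NRF2 targets, the genes of the oxidative stress response, shifted upward after CCL1. Of 10 members 8 were positive, with a median of 0.28 (camera adjusted p = 2.73e-05, adjusted p = 0.628 with an estimated correlation, fry adjusted p = 0.552). The groups overlapped: relative to the untreated mean the list stood at 0.14, 0.39 and 0.35 in the CCL1 arrays. In the untreated arrays it stood at -0.13, -0.04 and 0.17. The quinone reductase gene Nqo1 had a log2 fold change of 1.00 (SE 0.29), the sulfiredoxin gene Srxn1 0.48 (SE 0.11), the glutathione synthesis gene Gclc 0.38 (SE 0.16) and Osgin1 0.36 (SE 0.09). Over all genes 0 members were called, while 3 were higher adjusted over the list alone. Serine, glycine and proline synthesis and ATF4 targets shifted upward too (11 of 14 positive, median 0.11, camera adjusted p = 0.0209, adjusted p = 0.656 with an estimated correlation). The cystine transporter gene Slc7a11 stood at 1.23 (SE 0.56) in that list, with 9.59 in CCL1 replicate 3 against 6.97 and 7.46 in replicates 1 and 2. That list did not pass without untreated replicates 1 or 3 (0.0543 and 0.224), and contractile genes not without untreated replicate 3 (0.312) or CCL1 replicate 2 (0.0694). Contractile genes shifted upward in 15 of 20 members (median 0.07, camera adjusted p = 0.0226, adjusted p = 0.656 with an estimated correlation), with the smooth muscle actin gene Actg2 at 0.33 (SE 0.08) and Acta1 at 0.62 (SE 0.21). Interferon response genes shifted upward in 15 of 18 (median 0.18, camera adjusted p = 0.0359, adjusted p = 0.656 with an estimated correlation), with the antiviral genes Cmpk2 at 0.56 (SE 0.30) and Rsad2 at 0.42 (SE 0.29). Relative to the untreated mean the interferon list stood at 0.75 in CCL1 replicate 3 and at -0.09 and -0.08 in replicates 1 and 2. Without CCL1 replicate 3 it turned downward (camera adjusted p = 0.0608), and without untreated replicates 1, 2 or 3 it did not pass (camera adjusted p = 0.0562, 0.117 and 0.0554).

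**Figure D2:**
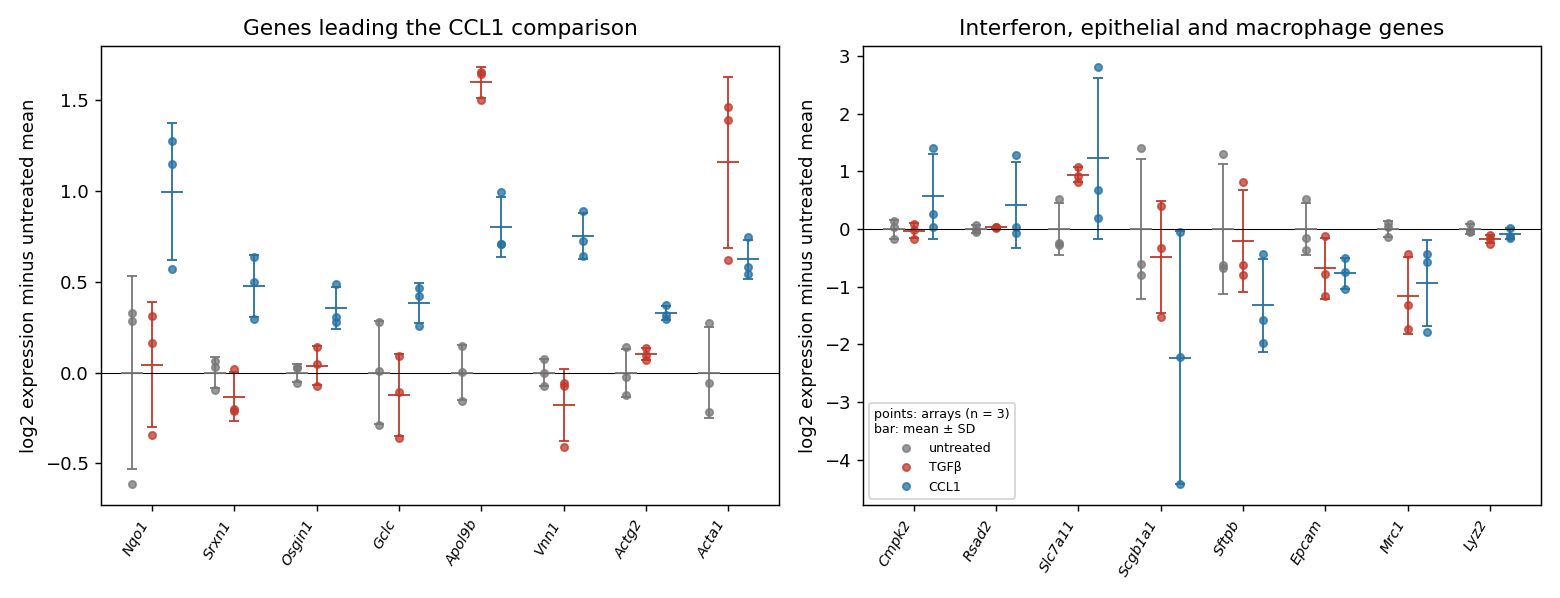
Log2 expression of 16 genes in each array, on the y axis as the difference from the mean of the untreated arrays, with genes on the x axis, arrays as points (n = 3 a group) and mean ± SD as bars. The left panel holds oxidative stress, contractile and other genes with Nqo1 at a difference of 1.00 after CCL1, and the right panel holds the cystine transporter gene Slc7a11 beside interferon, epithelial and macrophage genes, with Scgb1a1 at -2.23.

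Lists that shifted downward after CCL1 included markers of other lung cells. All 13 epithelial markers had negative values, with a median of -0.39 and a mean of -0.60 (camera adjusted p = 2.73e-05, adjusted p = 0.628 with an estimated correlation). The club cell gene Scgb1a1 had -2.23 (SE 1.01), the surfactant gene Sftpb -1.32 (SE 0.62) and Epcam -0.77 (SE 0.29). The epithelial marker mean was 7.07, 7.09 and 7.96 in the untreated arrays and 6.61, 7.29 and 6.41 in the CCL1 arrays. Endothelial markers shifted downward in 8 of 11 (median -0.21, camera adjusted p = 0.0359, adjusted p = 0.656 with an estimated correlation), with Egfl7 at -0.25 (SE 0.10). Without untreated replicate 3 (camera adjusted p = 0.636), CCL1 replicate 1 (0.158) or CCL1 replicate 3 (0.263) they did not pass, and with the epithelial covariate, chosen after seeing the data, they turned upward (0.548). Resting fibroblast markers shifted downward in 10 of 13 (median -0.12, camera adjusted p = 0.0444, adjusted p = 0.628 with an estimated correlation), with the growth factor receptor gene Pdgfra at -0.52 (SE 0.17) and Inmt at -0.97 (SE 0.38), and did not pass without untreated replicates 2 or 3 (0.0855 and 0.312) or CCL1 replicate 3 (0.203). All 15 cholesterol synthesis genes were negative (median -0.13, camera adjusted p = 0.0209, adjusted p = 0.656 with an estimated correlation), and that call ended without untreated replicate 2 (0.207) or CCL1 replicate 3 (0.191). Glycolysis and hypoxia genes were negative in 9 of 12 (median -0.13, camera adjusted p = 0.0209, adjusted p = 0.628 with an estimated correlation), with the pyruvate dehydrogenase kinase gene Pdk1 at -0.40 (SE 0.11) and Bnip3 at -0.59 (SE 0.30), and the call ended without untreated replicate 3 (0.146). Macrophage markers did not pass (median -0.09, camera adjusted p = 0.307).

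Matrix lists did not pass after CCL1. Camera adjusted p-values were 0.307 for collagen chains (median -0.02), 0.239 for matrix glycoproteins (median -0.02) and 0.707 for crosslinking enzymes, whose median was -0.02 and mean 0.02, and 0.307 for matrix proteases (median -0.08). TGFβ targets had a median of 0.07 (camera adjusted p = 0.225), with Hbegf at 0.51 (SE 0.13). Without CCL1 replicate 2 limma called 1 gene, the antimicrobial lectin gene Reg3g (-5.54, SE 0.46, adjusted p = 0.0316), which was named after its values were seen. In CCL1 replicates 1 and 3 it lay at 3.23 and 3.63, under the lower quartiles of all rows (3.92 and 3.91), so the size of the fall is not exact. With the epithelial marker mean as a covariate, an alternative chosen after seeing the data, camera passed 1 list instead of 9. The epithelial list was bound to lose its call in that fit, since the covariate is its own mean.

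**Figure D3:**
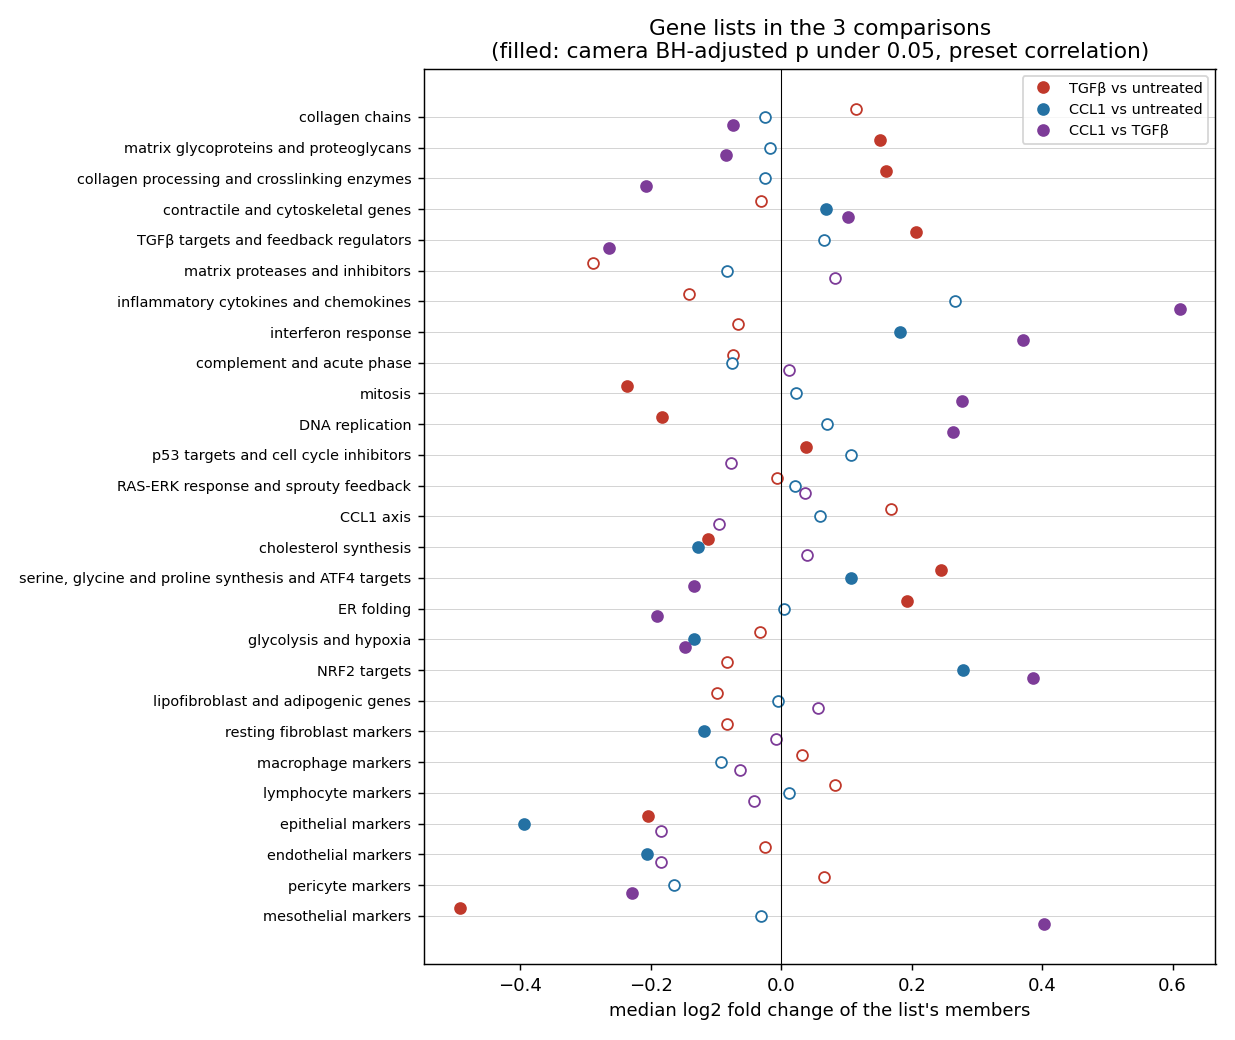
Median log2 fold change of the 27 gene lists on the x axis, with lists on the y axis and the 3 comparisons as points of different colours in 1 panel (n = 3 arrays a group). Filled points mark a camera Benjamini-Hochberg adjusted p under 0.05, which 11 lists reached for TGFβ, 9 for CCL1 and 15 for CCL1 against TGFβ.

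The last comparison set CCL1 directly against TGFβ. Adm was 3.03-fold higher with CCL1 than with TGFβ (log2 fold change 1.60, SE 0.18, n = 3 and 3 arrays), and the B cell chemokine gene Cxcl13 2.94-fold (1.56, SE 0.20). The adhesion gene Cdh10 was 3.45-fold lower (-1.78, SE 0.27), Ccl17 3.35-fold lower (-1.75, SE 0.17) and Has2 2.68-fold lower (-1.42, SE 0.12). Limma with Benjamini-Hochberg adjustment called 57 genes, 23 higher and 34 lower, of which 15 differed at least 2-fold. Unadjusted p-values under 0.05 numbered 2310.

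Further called genes were Vegfd (1.14, SE 0.15), Aldh1a1 (1.07, SE 0.12), Prkar2b (1.00, SE 0.12), Tfpi2 (-1.36, SE 0.17) and the matrix gene Thbs2 (-1.33, SE 0.15). From the lists, Pmepa1 (-0.89, SE 0.11), Id1 (0.92, SE 0.13) and the angiogenic factor gene Vegfa (-0.86, SE 0.12) were called as well. Of the 57 genes 21 were also called for TGFβ against untreated cells, a comparison that uses the same TGFβ arrays. The 3 arrays of CCL1 lay on one side of the 3 of TGFβ in 13.0% of genes, where chance gives 10%.

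Cell cycle lists were higher with CCL1 than with TGFβ. All 19 mitosis genes were positive (median 0.28, camera adjusted p = 2.24e-11, adjusted p = 0.189 with an estimated correlation), with Birc5 at 0.57 (SE 0.13). DNA replication genes were positive in 18 of 19 (median 0.26, camera adjusted p = 2.24e-11, adjusted p = 0.0957 with an estimated correlation), with Gins1 at 0.69 (SE 0.12). Over all genes 0 members of both lists were called, against 9 mitosis and 13 replication genes adjusted over the list alone. NRF2 targets were positive in 9 of 10 (median 0.39, camera adjusted p = 1.35e-06, adjusted p = 0.165 with an estimated correlation), with 0 called over all genes, 7 higher adjusted over the list alone and Srxn1 at 0.61 (SE 0.11). Mesothelial markers were positive in 8 of 8 (median 0.40, camera adjusted p = 0.000928, adjusted p = 0.251 with an estimated correlation). Interferon genes (median 0.37, camera adjusted p = 0.000159, adjusted p = 0.476 with an estimated correlation), inflammatory genes (median 0.61, camera adjusted p = 0.00399, adjusted p = 0.604 with an estimated correlation) and contractile genes (median 0.10, camera adjusted p = 0.00343, adjusted p = 0.464 with an estimated correlation) were higher too. The inflammatory list stood at 1.36 in CCL1 replicate 3 and at -0.34 and 0.03 in replicates 1 and 2, relative to the untreated mean. Without CCL1 replicate 3 neither the inflammatory list (camera adjusted p = 0.400) nor the interferon list (0.581) passed, and without TGFβ replicate 2 the inflammatory list did not (0.0624).

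Crosslinking, glycoprotein and collagen lists were lower with CCL1 than with TGFβ. Crosslinking enzymes were negative in 12 of 15 (median -0.21, camera adjusted p = 3.32e-05, adjusted p = 0.0957 with an estimated correlation), with Bmp1 at -0.43 (SE 0.09) and 5 lower adjusted over the list alone against 0 over all genes. Matrix glycoproteins were negative in 16 of 21 (median -0.09, camera adjusted p = 6.40e-05, adjusted p = 0.181 with an estimated correlation), with the elastin gene Eln at -0.88 (SE 0.15) and 7 lower adjusted over the list alone against 1 over all genes. Collagen chains were negative in 15 of 20 (median -0.07, camera adjusted p = 0.0154, adjusted p = 0.337 with an estimated correlation). TGFβ targets were negative in 13 of 21 (median -0.26, camera adjusted p = 0.00505, adjusted p = 0.134 with an estimated correlation). ER folding genes were negative in 13 of 13 (median -0.19, camera adjusted p = 8.77e-06, adjusted p = 0.217 with an estimated correlation), and serine, glycine and proline genes in 11 of 14 (median -0.13, camera adjusted p = 0.0154, adjusted p = 0.516 with an estimated correlation). Glycolysis genes (median -0.15, camera adjusted p = 0.0154, adjusted p = 0.426 with an estimated correlation) and pericyte markers (median -0.23, camera adjusted p = 0.0219, adjusted p = 0.181 with an estimated correlation) were lower too, while epithelial markers did not pass (median -0.18, camera adjusted p = 0.184). Matrix proteases and inhibitors did not pass and had a median of 0.08 (camera adjusted p = 0.669), with 3 higher and 4 lower adjusted over the list alone. Without CCL1 replicate 3 collagen chains (0.0746), glycolysis genes (0.0525) and pericyte markers (0.0800) did not pass, without TGFβ replicate 1 serine genes (0.248), glycolysis genes (0.431) and pericyte markers (0.0581) did not. Collagen chains (0.0619) and pericyte markers (0.0720) did not pass without TGFβ replicate 3, nor serine genes without CCL1 replicate 2 (0.0769).

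The count of 57 calls became 387 without TGFβ replicate 1, with 279 higher and 108 lower, a balance opposite to that of the 57. It was 27 and 0 without TGFβ replicates 2 and 3, and 11, 4 and 31 without CCL1 replicates 1, 2 and 3. Where it was 0, limma gave 1965 unadjusted p-values under 0.05.

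Changes under both stimuli were set side by side over all genes. Of the 29 genes called for TGFβ, 22 had the same sign after CCL1. Hbegf, at 1.26 after TGFβ, had 0.51 after CCL1, Tnfrsf11b 1.38 and 0.39, and Ccl17 1.99 and 0.25. The median ratio of the CCL1 to the TGFβ value was 0.125, where simulated data with shared untreated arrays and no CCL1 effect gave 0.0116 on average (range -0.0663 to 0.0971, 100 simulations). The share with the same sign was 75.9%, against 53.3% in the simulations (28.6% to 78.3%). Over all genes the fold changes correlated with r = 0.408, where simulations with neither a TGFβ nor a CCL1 effect gave 0.501 (0.462 to 0.531). Their covariance was 0.0133, where those simulations gave 0.0119 (0.0107 to 0.0129). All simulations drew each gene independently, while related genes can move together in the arrays, such as mitosis genes (estimated correlation 0.485). The simulated ranges can therefore be too narrow and decide nothing here. Leaving out single arrays moved r from 0.355 to 0.511. Calls shared by both stimuli numbered 0, as limma called no gene for CCL1.

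**Figure D4:**
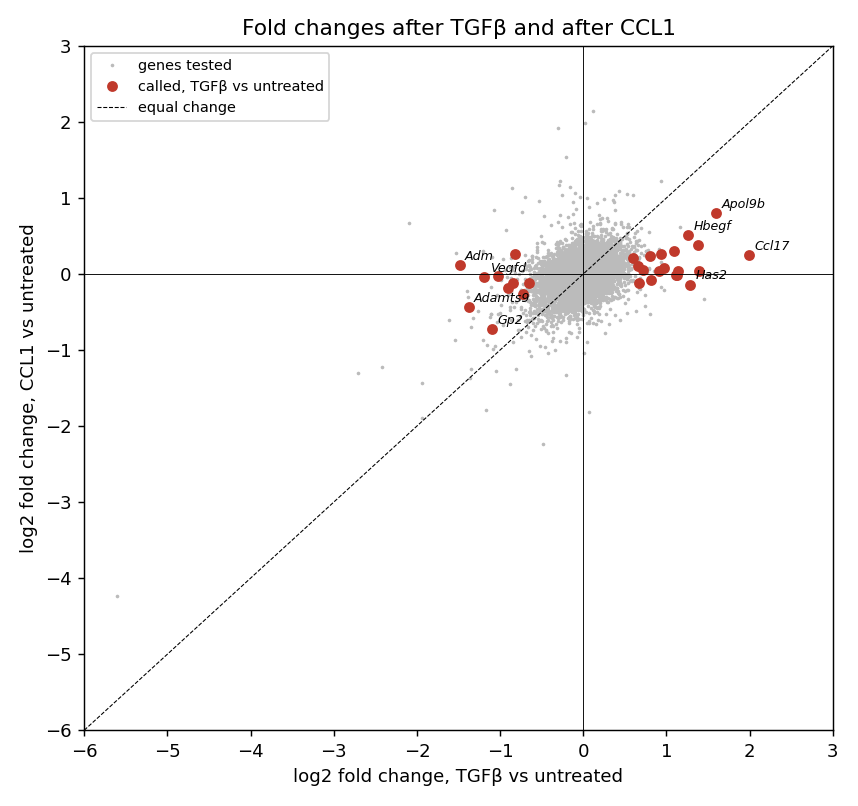
Log2 fold change after CCL1 on the y axis against that after TGFβ on the x axis for 22180 genes as points (n = 3 arrays a group), with the 29 genes called for TGFβ in red and equal change as a dashed line. Of the 29 red genes 22 had the same sign after both stimuli, and the correlation over all genes was 0.408.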

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

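The splits of arrays, the simulated 2-fold changes, the count without CCL1 array 3 and the list of activation genes were set before their results were seen, while all other tests in this part were chosen afterwards.

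Rows that carry no single gene name lie outside the gene tests, and signals in them were what drew notice. Among 17824 such rows, limma with adjustment over all rows passed 1 higher after TGFβ (adjusted p = 0.0133) and 2 for CCL1, at log2 fold changes of 1.32 (adjusted p = 0.0222) and -1.51 (adjusted p = 0.0170). The row higher after TGFβ is the one at 1.32 after CCL1, and no gene is listed for any of them.

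No gene passed for CCL1. Spread added by CCL1 array 3 stays open as an explanation, although 0 genes were called without CCL1 array 3. Leaving out an array also costs precision: the 29 TGFβ calls fell to 8, 11 or 12 without untreated replicates 1, 2 or 3. They fell too without TGFβ replicates 2 or 3 (16 and 9), and rose to 407 without TGFβ replicate 1. Precision too low for 2-fold changes stays open for part of the genes. Of simulated 2-fold changes in 200 genes 83.7% were called, but 36 genes had an absolute log2 fold change over 1 after CCL1 with 0 called, and for TGFβ 15 of 54 such genes were called. For 98.4% of genes the 95% interval excludes a 2-fold change after CCL1, and a smaller effect or none stays open.

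Genes of macrophage activation were high in CCL1 array 3. More macrophages in that culture does not account for it, since the macrophage marker mean lay at -0.0640 against CCL1 arrays 1 and 2 while the activation genes lay 0.75 higher. A response of that size to CCL1 in every culture does not either. The activation genes in CCL1 arrays 1 and 2 had a mean shift of -0.0634 against untreated. A weaker response in every culture stays open. Clec4e, named after its values were seen, lay at 6.76 and 7.15 in those arrays and at 6.14, 6.25 and 6.65 untreated. Il1b went the other way in CCL1 array 1, at 3.97 against 4.54, 4.42 and 4.90 untreated, and lay at 6.26 in CCL1 array 2. Of 20 listed activation genes 17 had their highest value in CCL1 array 3, a share that activation of macrophages already present predicted. The share decides little, since related genes were already high in that array. Relative to the untreated mean, the inflammatory list stood at 1.36 there and the interferon list at 0.75. A chance share of 11.1% holds only for independent genes and an array not picked from the data. Fibroblasts express some of the activation genes, Sod2 among them, and which cells responded was not tested.

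Airway secretory genes were low after TGFβ and in CCL1 arrays 1 and 3, with median log2 fold changes of -1.94 after TGFβ and -1.30 after CCL1 over 7 genes picked because they were low. An even loss of epithelial cells stays open: the 7 genes minus the epithelial markers shifted by -2.15 after TGFβ, in a form of the test adopted after another had been run, but their choice favours such a gap, and only Gp2 passed over all genes. Gp2 had -1.09 (limma adjusted p = 0.0381) and, with the epithelial markers as a covariate, -1.02 (limma adjusted p = 0.0623). A loss of airway cells stays open too, with ciliated cell genes at -0.16, -0.00 and -0.10 in the TGFβ arrays and -0.14, -0.15 and 0.29 untreated. So does a chance pick among secretory genes, since the other listed ones, whose median level of 4.81 lies under the 5.55 of all genes (noticed after the test), were negative in 11 of 15, lay at -0.18, -0.12 and -0.15 in the TGFβ arrays and -0.04, -0.04 and 0.08 untreated, and shifted by 0.14 against the epithelial markers.

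Splits of the 6 arrays of a comparison into 3 and 3 number 10, too few for a share under 0.05. For TGFβ 1 split reached the 29 called genes, the real one, and the highest other gave 0, and for lists 1 split reached 11, with 9 as the highest other. For CCL1 all 10 splits reached the 0 called genes, with 0 as the highest other, which shows nothing because any split reaches 0. For CCL1 lists 2 splits reached 9, with 11 as the highest other. For CCL1 against TGFβ 1 split reached 57 genes, with 1 as the highest other, and 1 split reached 15 lists, with 10 as the highest other.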

How the results depend on the processing

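The 31 called values of named genes kept their call in 368 of 526 cases under the alternatives and lost it in 158, Aldh1a1 after TGFβ keeping it in 7 of 17 and Gp2 in 8 of 16. Among named genes without a call 148 cases gained one, and no called gene reversed. The 35 list calls were kept in 525 of 665 cases, lost in 136 and reversed in 4, and 30 other cases gained a call. The reversed adjusted p-values were, after CCL1, epithelial markers 0.738 and endothelial markers 0.548 with the epithelial covariate, and interferon genes 0.0879 without TGFβ array 1 and CCL1 array 3 and 0.0608 without CCL1 replicate 3, within 0.000234 to 0.117 leaving out each array. For the epithelial list the covariate decides nothing, since it is the mean of that same list. Under 17 alternatives of camera the p53 list after TGFβ kept its call in 12 and the epithelial list in 10, and after CCL1 contractile genes kept it in 11 and interferon, resting fibroblast and endothelial lists in 9, while NRF2 targets kept it in all 17 but lost it with an estimated correlation (adjusted p = 0.628) and with fry (0.552), which are not among the 17. Called genes for TGFβ, 29 in limma, numbered 94 among genes at or above the median brightness, 281 with array weights (113 higher, 168 lower), 10 with only the 6 arrays compared, 10 over all rows and 15 with a minimum fold. They numbered 341 (78 higher, 263 lower) without TGFβ array 1 and CCL1 array 3 and 0 without the most epithelial arrays, both chosen after seeing the data. The epithelial covariate, which keeps all arrays, gave 22. Leaving out each array gave 8 to 407. For CCL1, 2 rows with no gene listed passed over all rows, and 0 to 1 genes leaving out each array. For CCL1 against TGFβ, 57, they numbered 157 among the brighter genes, 111 after quantile normalization, 105 with an intensity trend, 490 with array weights (274 higher, 216 lower), 0 with 6 arrays, 0 over all rows, 15 with a minimum fold, 113 without TGFβ array 1 and CCL1 array 3 and 0 without the most epithelial arrays. The epithelial covariate gave 39. Leaving out each array gave 0 to 387. Lists for TGFβ numbered 0 with an estimated correlation, 3 with fry and 8 to 12 leaving out each array. For CCL1 they numbered 4 among the brighter genes, 1 with the epithelial covariate, 0 with an estimated correlation, 0 with fry and 5 to 9 leaving out each array. For CCL1 against TGFβ they numbered 9 without TGFβ array 1 and CCL1 array 3, 0 with an estimated correlation, 8 with fry and 10 to 16 leaving out each array. The correlation of fold changes was 0.332 without TGFβ array 1 and CCL1 array 3, and 0.355 to 0.511 leaving out each array, and shared calls numbered 0 to 1. Apart from fewer arrays or a different number of tests, the cause was not tested. With 3 arrays a group, the median 95% interval reached 0.25 log2 to each side.

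A replicate block on the array numbers gave 18 calls for TGFβ, 0 for CCL1 and 3 for CCL1 against TGFβ. The numbers did not pair the arrays, since 1 of 9 pairs with the same number correlated over 0.1 (-0.12 to 0.19), and 2 of 9 arrays correlated best with their own number. The cause was not tested.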

Other observations

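Genes in this part were named after their values were seen, apart from Sod2 and Nos2 of the activation list, and no further hypothesis was tested here.

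Several airway defence genes had their lowest group means after TGFβ, with values as low in CCL1 arrays 1 and 3. Gp2 was an exception, at 4.21, 4.22 and 4.02 in the CCL1 arrays against 3.57, 3.96 and 3.83 after TGFβ. Relative to the untreated mean, the 7 genes noticed had a mean of -2.53, -2.53 and -2.24 in the TGFβ arrays and of -2.70, 0.29 and -2.75 in the CCL1 arrays. Reg3g, an antimicrobial lectin, lay at 8.02, 8.96 and 9.95 in the untreated arrays, at 3.24, 3.57 and 3.31 after TGFβ and at 3.23, 7.37 and 3.63 after CCL1. Its log2 fold change after TGFβ was -5.60 (SE 0.94, limma adjusted p = 0.0839). The TGFβ values of Reg3g lay under the lower quartile of all rows in those arrays (3.89 to 3.95), so the fall is not exact and could be larger. Bpifa1 had -2.71, Scgb3a1 -2.42, the lactoferrin gene Ltf -1.93 and the mucin gene Muc5b -1.35, and only Gp2 (-1.09, limma adjusted p = 0.0381) passed.

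Cytokine genes stood out in CCL1 array 3. Tnf lay at 10.71 there, 4.01 above the highest other array, Il1b at 10.06, 3.80 above, and the itaconate enzyme gene Acod1 at 10.08, 4.80 above. The neutrophil chemokine gene Cxcl2 lay 3.15 above and Sod2 0.98 above, while Nos2 was not highest in that array. Over the 3 arrays after CCL1 the log2 fold change of Il1b was 2.14 (SE 1.17, limma adjusted p = 0.852) and that of Tnf 1.54 (SE 0.90, limma adjusted p = 0.860).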
